A study of Mus musculus with 36 samples.

How the data were processed

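Polyadenylated RNA from mouse embryonic stem cells in which doxycycline (dox) switches on a Mesp1 transgene was sequenced, and 36 libraries were used here. The deposited files hold whole read counts per Ensembl gene for 49671 gene identifiers in each library. Per the submitters' processing notes the counts were made with Trimmomatic, STAR, HTSeq and DESeq2 on the mm10 genome build. Their versions, order and settings, the gene annotation and the use of strand are not given in the sources used here. The gene totals of a library ran from 12126604 to 51940589 counts, so that 1 count stood for 0.0193 to 0.0825 CPM (counts scaled to a common library total, the gene total of each library being the divisor). Counting error sets a lower limit on precision only, since reads without molecular identifiers are not independent molecules.

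Symbols and coordinates were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names, which gave a symbol to 49326 identifiers and coordinates to 49412. Exons of 38844 of these genes overlapped no exon of another gene. Since strand use is not stated, reads of genes that overlap on opposite strands cannot be told apart, and values of such genes are uncertain. The share of shared exon bases was 27.3% for Hoxb2, 52.9% for Hoxb3, 43.4% for Gbx2, 27.2% for Hopx, 23.2% for Ccn2, 20.5% for Dll1, 19.6% for Hand2, 16.8% for Sox17, 13.9% for Map3k15, 12.9% for Hes7, 12.5% for Eras and 47% for Rpl24, and at most 11.2% for the other protein-coding genes named.

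Samples were grouped by the labels' batch, genotype, time, treatment and sort. The comparisons, their samples and covariates, the gene lists and the rule for named genes were fixed before the data were examined. Batches 1 and 2 (18 libraries) were fitted together with batch as a term for the effects of dox at 12 h and 24 h, of time without dox, and of the differences between dox effects. Batch 3 (Zic2 knockout against wild type), the 2i libraries, and the sorted day 4 libraries were fitted on their own. The difference between the dox effects in 2i and at 24 h came from a joint fit of the 2i libraries with batches 1 and 2. The comparison of double positive with double negative cells used replicates 3 to 5 of each. That of double positive with unsorted cells used replicates 1 and 2 of each, and its values from double positive replicates 3 to 5 are given beside it because the libraries of replicates 1 and 2 differed from them.

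Genes were kept by filterByExpr on the groups, scaled by TMM, and tested with edgeR 4.0.16 (robust quasi-likelihood F test, 2-sided, R 4.3.3, files read with the R package data.table, version 1.17.8). P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p below 0.05. Standard errors (SE) are those of the log2 fold change. The p-values measure the spread between these libraries, and the labels do not say that replicates were separate cultures. A gene with no count in a group was compared with a floor of 3 counts over that group. The edgeR steps were tested on simulated data before use, in which unchanged genes had the same mean level in every group and batch. Changed genes were drawn from those with a mean of at least 1 CPM, so that recovery of weaker genes was not measured. Libraries were simulated as independent of one another, with no deviation shared between same-numbered ones. Power in the real data can thus be lower, as in 2i, where Mesp1 rose by 6.9 (log2) without a call. Of 100 genes changed 2-fold and 100 changed 4-fold among the genes of each comparison, the simulation recovered 69 and 96 at 24 h of dox, 43 and 86 at 12 h, 68 and 97 for 24 h against 0 h, 40 and 84 for the knockout, 30 and 73 for 2i, 60 and 90 for double positive against double negative, and 79 and 98 for double positive against unsorted. Of the genes called in it, in the same order, 4.62%, 7.86%, 8.33%, 11.4%, 16.9%, 5.66% and 19.2% (8, 11, 15, 16, 21, 9 and 42 genes) were unchanged, which is above the 5% aimed at in 6 of the 7, with 1 simulation each.

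The 23 gene lists, written from general knowledge, covered naive pluripotency, primed epiblast, primitive streak, paraxial and presomitic mesoderm, cardiac progenitor regulators, cardiomyocyte structure, endothelial, blood, mesenchymal and EMT (epithelial to mesenchymal transition), epithelial, neuroectoderm, definitive endoderm, visceral and extraembryonic endoderm, trophoblast, primordial germ cell, Wnt, BMP and FGF responses, the Nodal and Notch pathways, early Hox, proliferation and dissociation stress. Each was tested with camera (limma 3.58.1, 2-sided, preset correlation 0.01, adjusted over the 23 lists), which compares a list with all other genes. Camera with an estimated correlation is given beside it. Counts of a list are out of its members tested in that comparison, which can be fewer than those listed and differ between comparisons. Fry, which asks whether the genes of a list move on balance one way, was an alternative. Genes with at least a 2-fold change (absolute log2 of at least 1) and a call at 24 h of dox formed a Mesp1-induced and a Mesp1-repressed set, without Mesp1 itself, tested in 4 other comparisons and adjusted over 8 tests.

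Named genes followed a rule. It took Mesp1 everywhere, genes of the Zic family in the knockout, and Kdr and Pdgfra in sorted cells. It took the 6 higher and 6 lower called protein-coding genes with the largest fold change, a mean log2 CPM of at least 3 and no overlap of groups within a batch. It also took up to 4 members of a list with the smallest adjusted p, and called members that went against a list's majority, of which examples are given. Genes outside the rule are marked where they appear, and 2 results that it took are not reported here.

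Alternatives were DESeq2 size factors in edgeR, no count filter, a filter of 1 CPM in 2 samples, DESeq2 1.42.0 as the test, a non-robust fit, leaving out each library, fewer or more groups in a fit, batches alone or without a batch term, and the replicate number as a block. Genes without exon overlap, other choices of library, the block for double positive against unsorted cells and for the Mesp1 sets, and the streak list without Mesp1 were added after the data were seen. Libraries of double positive and double negative cells with the same number deviated together (correlations 0.46, 0.59 and 0.57, against at most 0.14 for other pairs), so that values with this pairing are given where they change a call. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, NumPy 2.4.6). HTSeq's summary tallies were used only to describe libraries.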

Results

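RNA-seq read counts were compared across 36 libraries of mouse embryonic stem cells that carry the mesoderm transcription factor gene Mesp1 under dox control. The growth record gives hanging drop differentiation from 1000 cells in serum for every library, including those labelled 2i. Hours are counted from a labelled differentiation stage. Batch 1 held 2 libraries each at 0 h, 12 h without dox, 12 h with dox, 24 h without dox and 24 h with dox. Batch 2 held 2 libraries at 0 h, 2 at 24 h without dox and 4 at 24 h with dox. Batch 3 held 2 wild-type and 2 Zic2 knockout libraries, all at 24 h with dox. A further 2 libraries without and 2 with dox were labelled as stem cells in 2i, a medium with a pair of kinase inhibitors that holds stem cells in the naive state. On day 4, 5 libraries were made from cells sorted as double positive for Flk1 (the product of Kdr) and Pdgfra, 3 from double negative cells, and 2 from unsorted (bulk) cells. The bulk titles carry the tag ND, which they do not explain, and the titles of the sorted libraries name no dox treatment. Whether bulk and sorted cells differed in treatment cannot be told from the titles.

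Gene totals per library were 12325443 to 46525179 counts in batch 1, 12360120 to 17484452 in batch 2, 13783028 to 15967343 in batch 3 and 13739481 to 19581884 in 2i. They were 50260410 to 51940589 for bulk, 17644613 to 19874949 for double positive replicates 1 and 2, 12126604 to 13372107 for double positive replicates 3 to 5, and 12642216 to 13655955 for double negative cells. In batch 2, 158 of the 9156 genes with a mean log2 CPM above 4 in batch 1 had no count in any of its 8 libraries. No gene showed the reverse, and none of the 158 was at 0 in all batch 3 libraries. Spread between replicates exceeded counting error in every group, with the variance at least 4.474 times that of counting alone.

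Mesp1 (ENSMUSG00000030544, chromosome 7, 79792241 to 79793788 on GRCm38) starts the mesoderm programme of heart and head precursors in the embryo. It was near 0 before differentiation advanced, at 0.224 and 0.382 CPM in the 0 h libraries of batch 1 and 0.532 and 0.386 in those of batch 2. Without dox it then rose in batch 1, to 4.58 and 5.98 CPM at 12 h and 41.5 and 45.3 at 24 h, but stood at only 0.808 and 1.5 CPM at 24 h in batch 2. Dox brought it to 208 and 322 CPM at 12 h, to 183 and 348 at 24 h in batch 1, and to 544, 209, 42.9 and 95.2 at 24 h in batch 2. It stood at 82, 47.2, 74.1, 87.3 and 67.5 CPM in double positive cells, 7.03, 9.57 and 8.37 in double negative cells and 55.8 and 74.3 in bulk. The counts do not separate transgene from endogenous transcripts.

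**Figure D1:**
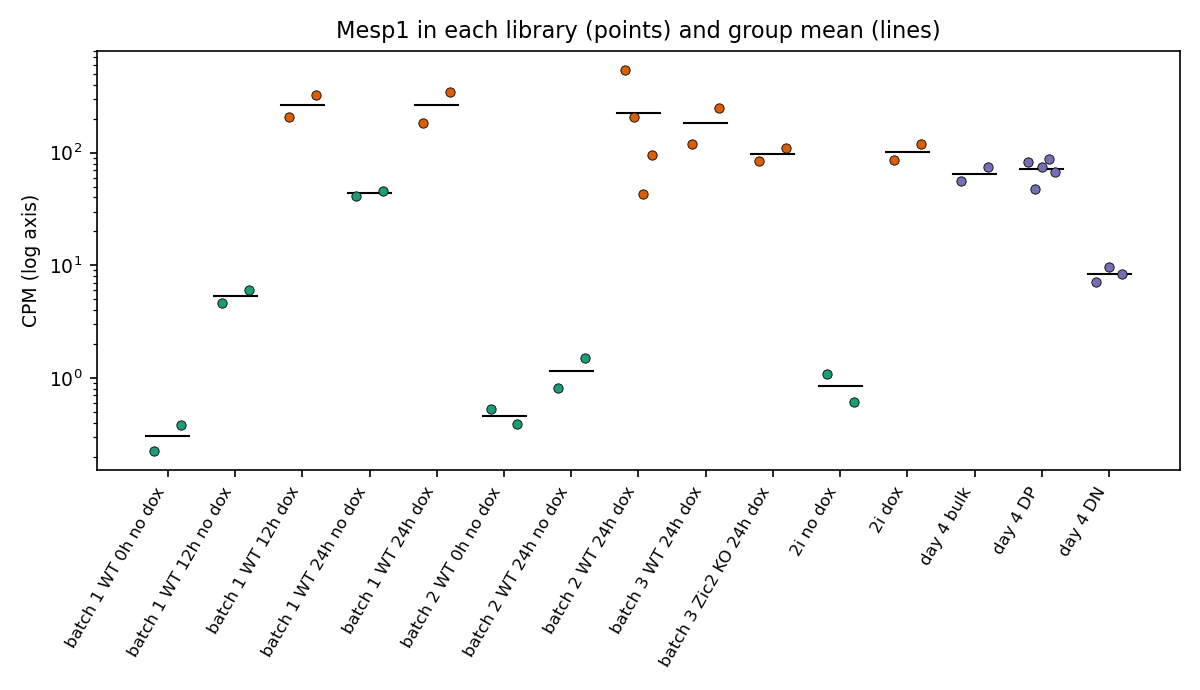
Mesp1 in each of the 36 libraries, with CPM on a log axis and the groups along the other axis. Each point is 1 library and each line a group mean; dox libraries range from 42.9 to 544 CPM in batches 1 and 2 and stand at 85.4 and 119 in 2i.

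The comparison at 24 h asked which genes change when Mesp1 is induced in differentiating cells. No library with dox is labelled as lacking the transgene. Effects of dox itself thus cannot be told apart from those of Mesp1, here and in the other dox comparisons. Genes of paraxial mesoderm, of mesenchyme and of the anterior Hox clusters rose, while genes of endoderm, epithelium and the epiblast fell. Foxc2, a forkhead gene of somites and head mesenchyme, went from 0.606 ± 0.666 CPM (SD, n = 4) to 150 ± 92.8 (n = 6), and Hoxb2, a patterning gene of the hindbrain and neighbouring mesoderm, from 0.222 ± 0.296 to 34.7 ± 33. Foxa2, which specifies endoderm and axial mesoderm, fell from 125 CPM to 2.7. Notch1, a receptor of the Notch pathway, rose from 39.3 to 629 CPM, and Pdgfra, a growth factor receptor of mesoderm, from 64 to 602.

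edgeR called 5584 of 18592 genes, 2869 higher and 2715 lower with dox, of which 1447 and 1427 changed at least 2-fold. Mesp1 itself rose by 4.52 ± 0.93 (log2 ± SE, edgeR adjusted p = 0.00116), by 2.63 in batch 1 and 7.61 in batch 2. The 6 strongest risers by the rule were Foxc2 (8.16 ± 0.69, edgeR adjusted p = 1.41e-07), Hoxb3 (7.60 ± 0.41, 1.84e-09), Prrt1 (7.52 ± 0.51, 1.27e-08), Hoxb2 (7.44 ± 0.34, 4.8e-10), Pgm5 (7.44 ± 0.77, 1.13e-06) and Chodl. Chodl, a membrane lectin gene, had 6268 counts with dox and 0 without and was at least 1450-fold higher (edgeR adjusted p = 5.52e-08). The 6 strongest that fell were Foxa2 (−5.50 ± 0.37, edgeR adjusted p = 1.37e-08), the stem cell Ras gene Eras (−5.02 ± 0.23, 4.8e-10), Slc27a2 (−5.0 ± 0.33, 1.19e-08), Trim67 (−4.91 ± 0.48, 6.32e-07), the organizer gene Gsc (−4.83 ± 0.52, 1.98e-06) and Upp1 (−4.26 ± 0.28, 9.38e-09). Of the 43 genes named for this comparison, 41 had every dox library beyond every library without dox in the same batch, which random labels within batches give for 2.22% of unchanged genes. The rule took many named genes for such separation or for a small p, here and below, so that these tallies are no separate evidence. The exceptions were Mesp2 (3 of 6 dox libraries) and Msgn1 (2 of 6).

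Foxc2 lies on chromosome 8 at 121116171 to 121118895 (ENSMUSG00000046714), Hoxb2 on chromosome 11 at 96350525 to 96354012 (ENSMUSG00000075588), Foxa2 on chromosome 2 at 148042877 to 148046969 (ENSMUSG00000037025) and Eras on chromosome X at 7924276 to 7928607 (ENSMUSG00000031160), all on GRCm38. Fitted alone, batch 1 called 3854 genes (1827 higher and 2027 lower) and batch 2 called 3118. They shared 1032 higher and 1045 lower genes, where independent lists would share 170.4 and 177.6, and 19 genes called in both went opposite ways (5 and 14). Without a batch term 3736 genes were called (1935 higher and 1801 lower).

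**Figure D2:**
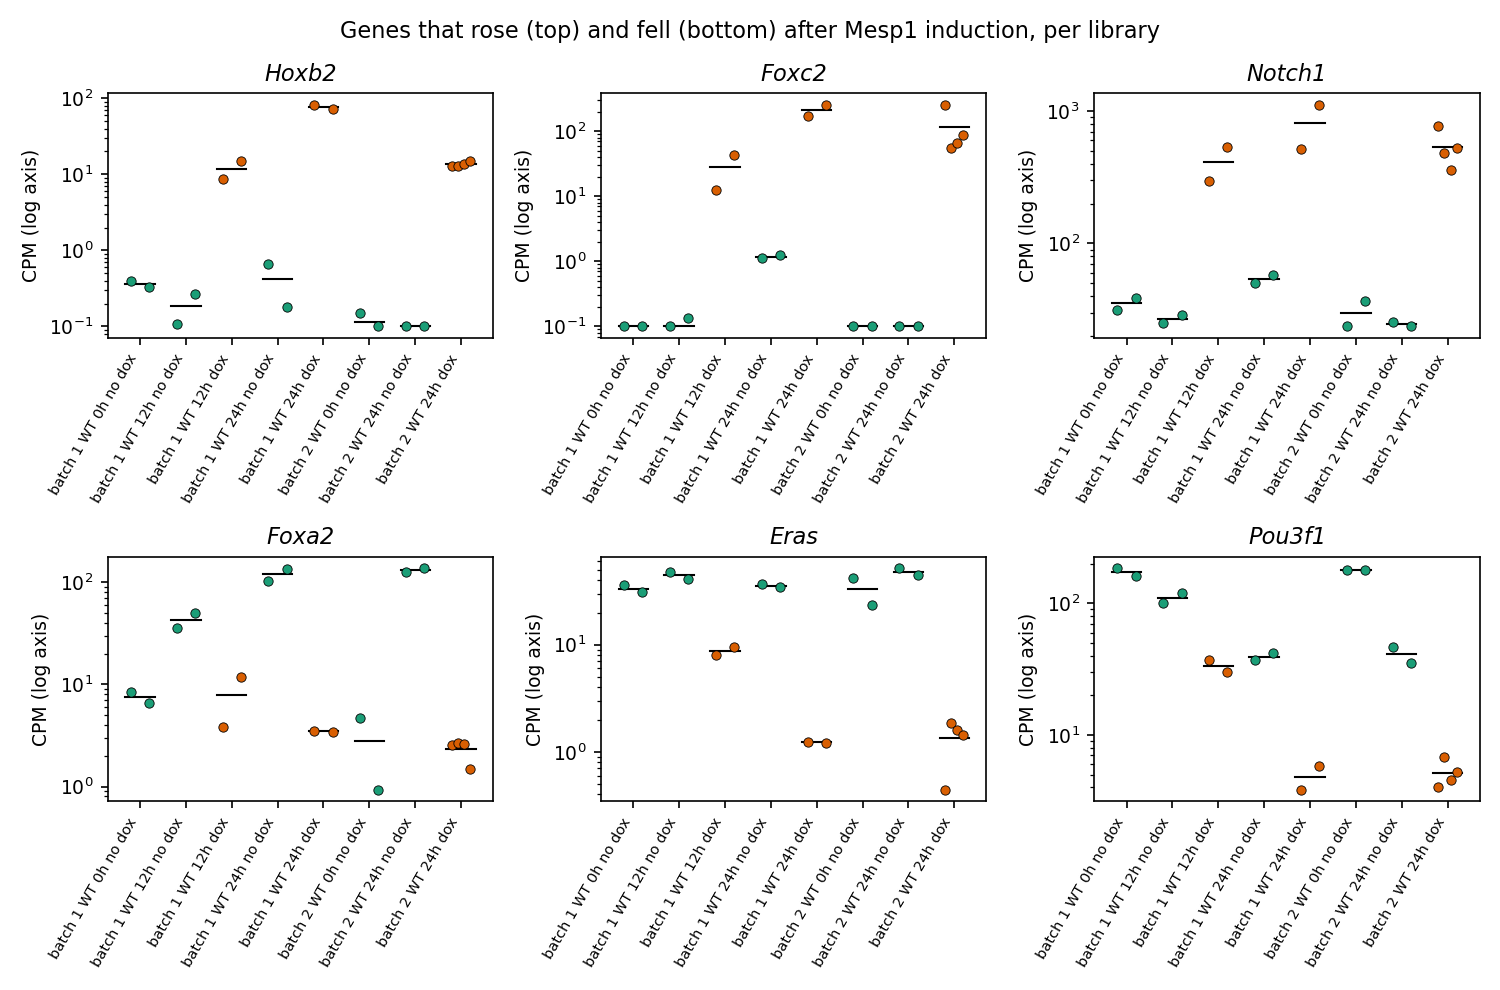
Hoxb2, Foxc2, Notch1, Foxa2, Eras and Pou3f1 in the libraries of batches 1 and 2, as CPM on a log axis by time and treatment, with values under 0.1 CPM drawn at 0.1. Points are libraries and lines are group means, and the dox libraries stand above or below all libraries without dox of the same batch at 24 h.

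Mesoderm lists rose with dox at 24 h. Of 18 paraxial and presomitic mesoderm genes, 14 rose, 2 fell and 2 were not called (median 2.99, camera adjusted p = 4.09e-08, 0.0399 with an estimated correlation). They included Aldh1a2, which makes retinoic acid (6.31, edgeR adjusted p = 3.36e-08), and the Notch modulator Lfng (4.23, 1.82e-08). The 2 that fell were the segmentation gene Mesp2 (−2.19 ± 0.64, edgeR adjusted p = 0.0141) and Msgn1, with 68 counts without dox and 2 with it. Mesp2 fell by 3.34 in batch 1 and stood at 0.11 (edgeR adjusted p = 0.898) in batch 2, and without batch 1 dox library 1 it was not called (−1.85, 0.0657). Of 19 cardiac progenitor regulators 14 rose, such as Foxf1 (5.07, edgeR adjusted p = 8.67e-07), Wnt2 (4.13, 9.47e-06) and the smooth and heart muscle coactivator Myocd (7.00 ± 0.71, 1.03e-06), and only Hopx fell (−2.39, 3.84e-05; list median 2.27, camera adjusted p = 3.43e-07, 0.042 estimated). Of 14 early Hox genes listed 8 were tested, and all 8 rose. Genes could pass the count filter through the dox libraries alone. Hoxb1 rose by 6.23 (edgeR adjusted p = 2.54e-07; list median 6.09, or 5.44 with the gene at 0 held at its bound, camera adjusted p = 2.76e-11, 0.00876 estimated).

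Genes that dismantle epithelium moved with them. Of 17 mesenchymal and EMT genes 13 rose, among them Zeb1 (4.93 ± 0.38, edgeR adjusted p = 4.9e-08) and Twist1 (3.90, 4.78e-07), and 4 were not called (median 1.74, camera adjusted p = 5.54e-09, 0.0137 estimated). Of 17 epithelial genes 14 fell and 3 were not called, led by the tight junction genes Ocln (−2.76, edgeR adjusted p = 4.8e-10), Cldn7 (−3.28 ± 0.22, 1.26e-08) and Marveld3 (−3.91, 2.09e-09; list median −2.12, camera adjusted p = 9.33e-21, 0.00876 estimated). In the Notch list, 6 of 9 genes rose, with Notch1 at 4.19 ± 0.32 (edgeR adjusted p = 4.25e-08), while the target Hes1 fell (−0.99, 4.5e-06; list median 2.31, camera adjusted p = 0.000126, 0.105 estimated). BMP response genes gave 6 higher and 1 lower of 12 (median 0.82, camera adjusted p = 0.0133, 0.098 estimated), and cardiomyocyte structure 5 higher of 16 (median 0.77, camera adjusted p = 0.0396, 0.206 estimated).

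Epiblast, streak and endoderm lists fell. Primed epiblast genes gave 12 lower of 16, including the POU factor Pou3f1 (−3.01 ± 0.15, edgeR adjusted p = 1e-09) and Otx2 (−1.68, 1.27e-07; list median −1.39, camera adjusted p = 6.93e-13, 0.0137 estimated). Of 15 primitive streak genes 11 fell, among them the activin antagonist Fst (−3.79 ± 0.20, edgeR adjusted p = 1.28e-09) and Fgf8 (−3.86, 1.74e-06), and the only riser was Mesp1 (median −2.56, camera adjusted p = 5.78e-10, 0.042 estimated). Definitive endoderm gave 8 lower of 11, and its 1 riser was Cxcr4 (2.82 ± 0.68, edgeR adjusted p = 0.00429; list median −2.25, camera adjusted p = 2.36e-06, 0.0262 estimated). Cxcr4 rose by 0.87 in batch 1 and 5.50 in batch 2, and was not called without a batch term (2.05, 0.055). Nodal pathway genes gave 7 lower of 10, such as Nodal (−3.13, edgeR adjusted p = 1.2e-07), with Foxh1 higher (1.04, 1.39e-05; list median −1.40, camera adjusted p = 0.000459, 0.0904 estimated). Naive pluripotency genes split, with 7 lower of 18, such as Nanog (−3.29 ± 0.33, edgeR adjusted p = 9.73e-07), and 4 higher, such as Gbx2 (2.21, 0.000401) and Klf4 (1.67, 0.00176; list median −1.0, camera adjusted p = 0.0165, 0.438 estimated).

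Primordial germ cell genes gave 3 lower of 8 (median −0.96, camera adjusted p = 0.01, 0.042 estimated) and FGF response genes 3 lower of 12 (median −0.57, camera adjusted p = 0.0133, 0.455 estimated). The other lists did not pass camera. Endothelial genes gave 7 higher and 1 lower of 17, among the higher Fli1 (5.35, edgeR adjusted p = 3.11e-08; list median 0.70, camera adjusted p = 0.0645, 0.455 estimated). Blood genes gave 2 higher, 1 of them Gata2 (5.06, edgeR adjusted p = 9.01e-09), and 3 lower of 10 (median −0.09, camera adjusted p = 0.733, 0.784 estimated). Neuroectoderm genes gave 5 higher, such as Lhx5 (4.03, edgeR adjusted p = 0.000148), and 4 lower of 12 (median −0.10 while the test pointed up, camera adjusted p = 0.491, 0.748 estimated). Visceral and extraembryonic endoderm gave 3 higher of 17 (median 0.06, camera adjusted p = 0.142, 0.662 estimated), trophoblast 2 higher and 2 lower of 9 (median 0.16 while the test pointed down, 0.696, 0.784 estimated) and Wnt response 4 higher and 3 lower of 12 (median −0.42 while the test pointed up, 0.123, 0.455 estimated). Proliferation genes gave 3 higher of 15 (median 0.09, camera adjusted p = 0.252, 0.478 estimated) and dissociation stress genes 2 higher and 5 lower of 14 (median −0.39, 0.121, 0.564 estimated).

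Adjusted over the list alone, the counts at 24 h were the same for paraxial mesoderm (14 higher, 2 lower), epithelial (14 lower), primed epiblast (12 lower) and early Hox (8 higher) genes, and rose to 13 lower for primitive streak, 16 higher for cardiac progenitor, 14 higher for mesenchymal, 9 lower for definitive endoderm and 7 higher for Notch genes. With an estimated correlation, 9 of the 15 lists that camera called at 24 h of dox remained below 0.05, 4 of them up and 5 down.

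**Figure D3:**
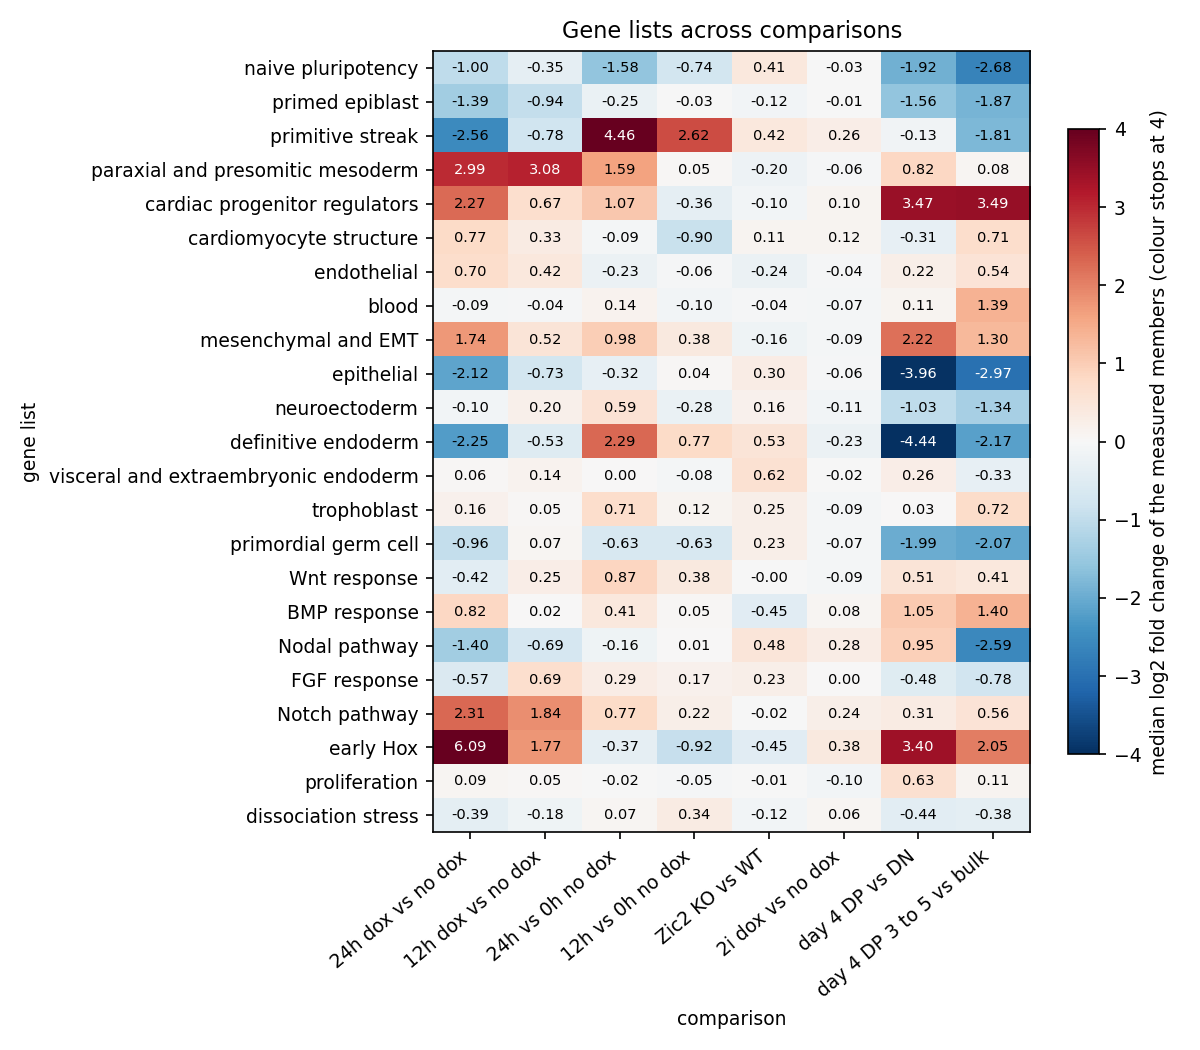
Median log2 fold change of each of the 23 gene lists, in a grid with lists along 1 axis and 8 comparisons along the other. Colour gives the median and stops at 4 in either direction, so that the early Hox median of 6.09 at 24 h of dox is drawn at the end of the scale.

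At 12 h, in 2 libraries against 2 of batch 1, the question was which of these changes come early. Paraxial mesoderm and early Hox genes had risen in part, and 5 of 17 epithelial and 6 of 16 primed epiblast genes were lower, the last 2 lists not holding with an estimated correlation. Hes7, a gene of the segmentation clock, rose by 5.95 (edgeR adjusted p = 1.55e-05), the Notch ligand gene Dll3 by 4.77 (0.000246), Lfng by 5.25 (2.26e-06) and Hoxb2 by 6.15 ± 0.47 (9.18e-07). The chemokine gene Cxcl12, whose product guides migrating cells, fell from 130 ± 13.1 to 21.5 ± 8.14 CPM (−2.57 ± 0.35, edgeR adjusted p = 0.000201).

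edgeR called 1052 genes at 12 h, 611 higher and 441 lower. Mesp1 rose by 5.69 ± 1.28 (edgeR adjusted p = 0.0119), and was not called without library 1 (0.179) or 2 (0.134) without dox or without dox library 2 (0.0634). The strongest risers were Foxc2 (8.80 ± 1.2, edgeR adjusted p = 0.000221), Tmem132c (7.59 ± 0.61, 1.64e-06), Kcnn3 (6.99, 4.46e-06), Pcdh19 (6.62 ± 0.52, 1.22e-06), Grin2c (6.51, 4.08e-05) and Chodl, which had 1 count without dox and 1347 with it (2.94e-05). The strongest that fell were Magel2 (−3.16, edgeR adjusted p = 0.000766), Foxd3 (−2.57, 0.000967), Cxcl12, Lypd6 (−2.50, 2.67e-05), Foxa2 (−2.44 ± 0.53, 0.00905) and Foxi3 (−2.43, 0.00715). Foxa2 was not called without library 2 without dox (0.0897) or dox library 1 (0.131), nor Foxi3 without library 2 without dox (0.0651), dox library 1 (0.0902) or dox library 2 (0.0575). All 22 genes named for this comparison had both dox libraries beyond both libraries without dox (33.3% by chance). Leaving out a library changed the count to 423 (238 higher and 185 lower, library 1 without dox), 501 (333 and 168, library 2 without dox), 693 (543 and 150, dox library 1) or 485 (323 and 162, dox library 2), the lower count falling most without dox library 1. Of the 611 and 441 genes, 547 and 417 were called the same way at 24 h, where independent lists would share 94.29 and 64.4.

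Paraxial and presomitic mesoderm led the lists at 12 h, with 10 of 18 genes higher (12 adjusted over the list alone; median 3.08, camera adjusted p = 3.02e-13, 0.0181 with an estimated correlation). Of 8 early Hox genes 3 rose (3 adjusted over the list alone; median 1.77, camera adjusted p = 5.64e-09, 0.0181 estimated). These 2 lists alone held with an estimated correlation. Camera also called Notch pathway genes with 4 higher of 9 (5 over the list alone; median 1.85, 3.71e-06, 0.132 estimated) and mesenchymal genes with 7 higher of 17 (median 0.52, 1.67e-05, 0.0936 estimated), among them Snai1, which represses E-cadherin (2.87, edgeR adjusted p = 0.00195; not called without library 1 without dox, 0.059). Epithelial genes gave 5 lower of 17 (median −0.73, camera adjusted p = 5.64e-09, 0.0936 estimated), led by Ocln (−1.94, edgeR adjusted p = 8.75e-06). Primed epiblast genes gave 6 lower and 1 higher of 16 (median −0.94, camera adjusted p = 6.91e-07, 0.0936 estimated), with Pou3f1 at −1.69 (edgeR adjusted p = 0.000127). Gata2, a blood and endothelial factor, rose by 5.64 (edgeR adjusted p = 4.34e-06), and the naive pluripotency ligand Fgf4 by 3.06 (0.0049; not called without library 1, 0.0641, or 2, 0.0963, without dox).

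The difference between the dox effects at 24 h and 12 h was tested as such. The 12 h effect came from batch 1 only and the 24 h effect from both batches. Dox effects at 24 h differed between batches for 117 genes, so that the difference in time also carries one between batches. Among 61 genes with a lower effect at 24 h, the stem cell gene Eras fell by 2.71 ± 0.38 more on the log2 scale (edgeR adjusted p = 0.00902), the endoderm gene Foxa2 by 3.06 more (0.0415) and the zinc finger gene Bcl11b by 2.77 ± 0.38 more (0.00793). The formin gene Fhod3, which builds heart muscle sarcomeres, rose more at 24 h (2.91 ± 0.45, edgeR adjusted p = 0.0186). Mesp1 was not called (−1.18 ± 1.44, edgeR adjusted p = 0.96). edgeR called 97 genes, 36 with a higher and 61 with a lower effect at 24 h. This count depended on each 12 h library, being 1 without either library without dox (Gm15737 both times, a gene outside the rule and noted after its values were seen), 7 without dox library 1 and 52 without dox library 2. It was 42 to 54 without a batch 1 library of 24 h (no dox 1 gave 52, no dox 2 gave 43, dox 1 gave 54, dox 2 gave 42), 43 without either batch 2 library without dox, and 194 and 249 without batch 2 dox library 1 and 2.

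Of 17 epithelial genes, 2 fell more at 24 h and 15 were not called (10 adjusted over the list alone; median −1.39, camera adjusted p = 7.2e-15, 0.054 with an estimated correlation). Primitive streak genes gave 1 lower of 15 (7 over the list alone; median −1.46, camera adjusted p = 1.23e-09, 0.0612 estimated). For cardiac progenitor regulators, 2 of 19 were higher when adjusted over the list alone (median 1.12, camera adjusted p = 3.16e-07, 0.054 estimated). FGF response genes gave 4 lower of 12 over the list alone (median −1.37, camera adjusted p = 1.62e-08, 0.092 estimated). No list held with an estimated correlation, against 14 called with the preset value, and the paraxial median was −0.18 while the test pointed up.

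Differentiation without dox was followed from 0 h to 24 h in both batches, 4 libraries against 4. Of 15 genes of the primitive streak, where mesoderm and endoderm arise, 13 rose, and 10 of 18 naive pluripotency genes fell. Mixl1, a homeobox gene of the streak, went from 4.39 to 205 CPM, the T-box gene Eomes from 43.1 to 560 and Foxa2 from 5.13 to 125. The naive pluripotency gene Nr0b1 fell by 3.78 on the log2 scale (edgeR adjusted p = 5.62e-06).

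edgeR called 4675 genes, 2503 higher and 2172 lower at 24 h. The strongest risers were the apelin receptor gene Aplnr (6.51 ± 0.83, edgeR adjusted p = 5.41e-05), Frzb (6.12, 7.1e-05), the Nodal antagonist Cer1 (5.84 ± 0.49, 1.48e-06), Klhl6 (5.60, 0.00247), Hand1 (5.59 ± 1.17, 0.00258) and Mesp1 (5.49 ± 1.32, 0.00644). The strongest that fell beside Nr0b1 were Rpl39l (−3.50, edgeR adjusted p = 0.000252), Rbmxl2 (−3.39, 1.04e-05), Fgf4 (−3.38, 7.56e-05), Gdf3 (−3.24, 0.00146) and Dppa2 (−3.17, 0.000219). All 21 genes named had every 24 h library beyond every 0 h library of its batch (5.56% by chance). Without batch 1 library 1 of 24 h, 1856 were called higher and 1312 lower. Batch 1 alone called 1875 higher and 1551 lower genes and batch 2 alone 468 and 190, with 325 and 130 shared where 51.56 and 17.45 would be by chance. In batch 2 alone Mesp1 (1.25, edgeR adjusted p = 0.736) and Hand1 (0.85, 0.826) were not called, nor were Fgf4 (−3.19, 0.0529) and Rpl39l (−3.08, 0.0837), whose folds were near the joint ones, nor Dppa2 (−2.29, 0.0774) and Gdf3 (−1.98, 0.184). Without a batch term 2089 genes were called, Dppa2 (−2.68, edgeR adjusted p = 0.0665) and Gdf3 (−2.51, 0.143) not among them.

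Of 15 primitive streak genes 13 rose and 2 were not called (14 adjusted over the list alone; median 4.46, camera adjusted p = 2.21e-17, 0.0652 with an estimated correlation). They included Mixl1 (5.44 ± 0.60, edgeR adjusted p = 1.64e-05), Eomes (3.59 ± 0.43, 3.69e-05), Wnt3 (2.40, 8.7e-06) and Fst (3.38 ± 0.23, 2.04e-07). Definitive endoderm genes gave 7 higher of 11 (8 over the list alone; median 2.29, camera adjusted p = 9.24e-07, 0.0652 estimated), with Foxa2 at 4.61 ± 0.42 (edgeR adjusted p = 3.26e-06). Wnt response genes gave 7 higher of 12, among them Sp5 (5.35, edgeR adjusted p = 0.000103) and Axin2 (2.41, 4.53e-05; list median 0.87, camera adjusted p = 9.27e-05, 0.131 estimated). Mesenchymal genes gave 7 higher and 1 lower of 17, such as Cdh11 (4.65, edgeR adjusted p = 1.27e-06; list median 0.98, camera adjusted p = 2.13e-05, 0.131 estimated). Naive pluripotency genes gave 10 lower of 18 (median −1.58, camera adjusted p = 1.65e-05, 0.272 estimated). Kdr, the Flk1 gene, rose by 4.47 ± 0.75 (edgeR adjusted p = 0.000507), by 6.24 in batch 1 and 1.53 in batch 2. None of the 9 lists that camera called held with an estimated correlation.

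The 12 h libraries came from batch 1 only, but were fitted together with batch 2, whose 0 h libraries thus enter the difference between 12 h and 0 h. The activin antagonist Fst rose by 2.43 ± 0.26 (edgeR adjusted p = 0.000265), Cdh11 by 2.95 ± 0.41 (0.00413), Mixl1 by 4.11 ± 0.64 (0.0107), Eomes by 2.83 ± 0.47 (0.0144) and Foxa2 by 2.78 (0.0143). Wnt3 (1.62, edgeR adjusted p = 0.0219), Cer1 (2.85, 0.0251), Gsc (3.28, 0.0347) and Evx1 (3.71, 0.0484) rose too, while Epas1 (−2.17, 0.0144), Radil (−1.58, 0.0181), Twf2 (−0.73, 0.0315) and Dusp9 (−1.14, 0.0347) fell. Mesp1 was not called (3.19 ± 1.56, edgeR adjusted p = 0.529), though its batch 1 mean went from 0.303 to 5.28 CPM, and fitting only the groups compared gave 4.02 (0.00117) for it and 488 genes in all. All 14 genes named had both 12 h libraries beyond both 0 h libraries of batch 1 (33.3% by chance). edgeR called 59 genes, 51 higher and 8 lower. This count was 35 and 11 without 0 h library 1 and 2, and 15 and 5 without 12 h library 1 and 2, and of the 13 called genes named only Fst kept its call in every one of these fits. Primitive streak genes gave 6 higher of 15 (12 adjusted over the list alone; median 2.62, camera adjusted p = 3.36e-30, 0.0146 with an estimated correlation), the only list to hold with an estimate. Definitive endoderm gave 3 higher of 11 (median 0.77, camera adjusted p = 0.000472, 0.212 estimated). For naive pluripotency the median was −0.75 (camera adjusted p = 0.000306, 0.494 estimated).

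Whether dox acted alike in both batches at 24 h was tested as an interaction. The chemokine receptor gene Cxcr4 (4.64 ± 0.39, edgeR adjusted p = 5.09e-05) and the growth factor gene Fgf3 (5.52 ± 0.49, 5.09e-05) had a higher effect in batch 2, as did Hs3st3b1 (5.12 ± 0.30, 9.25e-07), Klhl6 (5.91 ± 0.52, 5.09e-05) and the axon guidance receptor gene Robo3 (4.94, 0.00148). Map3k15 (−1.69, edgeR adjusted p = 0.000406) and Serinc5 (−1.47, 0.00329) had a lower effect in batch 2. edgeR called 117 genes, 103 with a higher and 14 with a lower effect in batch 2. Mesp1 was not called (4.99 ± 1.26, edgeR adjusted p = 0.121), but was without batch 2 dox library 1 (4.04, 0.04) or 3 (5.34, 0.0222). Leaving out a batch 1 library gave 46 (no dox 1), 56 (no dox 2), 28 (dox 1) or 59 (dox 2) genes. Leaving out batch 2 library 1 or 2 without dox gave 22 or 40, and dox library 1 gave 237.

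Prss12 (4.40, edgeR adjusted p = 0.0238), Ccn2 (−2.26, 0.00888), Aifm2 (−2.65, 0.014) and Car3 (−1.57, 0.0152) were called too but lost the call without batch 1 library 1 without dox (0.077, 0.0667, 0.0862 and 0.0749) or batch 2 library 1 without dox (0.248, 0.0548, 0.132 and 0.132). Other losses of these 4 were with batch 1 library 2 without dox (all but Ccn2), dox library 1 (all but Aifm2), dox library 2 (Prss12 and Aifm2) and batch 2 library 2 without dox (Prss12 and Car3). Primitive streak genes had a higher effect in batch 2 for 1 of 15 (10 adjusted over the list alone; median 2.03, camera adjusted p = 3.49e-15, 0.0231 with an estimated correlation). FGF response genes gave 2 higher of 12 (9 over the list alone; median 1.27, camera adjusted p = 2.29e-13, 0.0335 estimated), Notch genes 2 of 9 (5; 1.61, 2.36e-10, 0.0157) and cardiac progenitor regulators 5 higher and 1 lower of 19 (9 and 2; 1.01, 4.45e-09, 0.025). Lists of neuroectoderm (median 1.58, camera adjusted p = 1.26e-08, 0.00276 estimated), mesenchymal (0.54, 1.7e-07, 0.025), definitive endoderm (1.30, 1.7e-07, 0.0231) and trophoblast genes (1.76, 5.8e-05, 0.0157) also held with an estimate, 8 of the 17 that camera called.

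The knockout comparison asked what Zic2, a zinc finger gene of epiblast and neural plate, contributes to the state reached 24 h after Mesp1 induction, in 2 libraries against 2 of batch 3. Zic2 (ENSMUSG00000061524, chromosome 14, 122475435 to 122479852) stood at 108 and 74.7 CPM in the wild-type libraries and 73 and 56.4 in the libraries labelled knockout, so that the transcript was still present (−0.50 ± 0.22, edgeR adjusted p = 1). A deletion that leaves most exons in place would not show in gene totals, and the counts do not check the label. Mesp1 was at 120 and 248 CPM in wild type and 84.5 and 109 in the knockout (−0.93 ± 0.35, edgeR adjusted p = 1). Hoxb2, Hoxb3 and Foxc2, which dox had raised, had lower values in both knockout libraries than in either wild-type library, 20.9 and 20.4 against 56.3 and 41.1 CPM for Hoxb2 and 38.1 and 26.5 against 124 and 75.6 for Foxc2.

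edgeR called 0 of 16518 genes, with 390 at an unadjusted p below 0.05. The 390 are fewer than the share of 0.05 that unchanged genes would give. DESeq2 called 5 genes, all lower in the knockout. These were Hoxb3 (DESeq2 adjusted p = 0.000109; edgeR log2 −1.11 ± 0.13), Foxc2 (0.000201; −1.62 ± 0.29), the antisense transcript Hoxb3os (0.000447; −1.14), Hoxb2 (0.00126; −1.24 ± 0.19) and Grin2c (0.0202; −1.25), all named after their values were seen. Hoxb3os shares exon bases with both Hoxb2 and Hoxb3, so that these 3 are not separate evidence. Without wild-type library 2, edgeR called 9 genes. Zic1 (0.14) and Zic5 (0.07) were not called (edgeR adjusted p = 1 for each) and changed sign when a library was left out, Zic1 to −0.24 without knockout library 2, and Zic5 to −0.32 without wild-type library 2 and −1.12 without knockout library 1. Zic4 had 3 to 6 counts per library and was not tested. Of the 9 genes named and tested, 7 had both knockout libraries beyond both wild-type libraries (33.3% by chance), the exceptions being Zic1 and Zic5 (1 of 2).

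No list member was called by edgeR in the knockout. Camera gave visceral and extraembryonic endoderm (median 0.62, camera adjusted p = 3.52e-08) and epithelial genes (0.30, 1.64e-06) higher, early Hox genes lower (−0.45, 0.000198, with 2 of 8 lower adjusted over the list alone) and naive pluripotency genes higher (0.41, 0.00123), each at 0.59 with an estimated correlation. None of the 8 lists called by camera held with an estimate. As a set, the Mesp1-repressed genes had higher values in the knockout (median 0.24 over 1047 genes, camera adjusted p = 1.35e-11) and the Mesp1-induced genes lower ones (−0.09 over 1282 genes, 0.000301), and neither held with an estimated correlation (0.135 and 0.154). Mesp1 itself had lower values in both knockout libraries, without a call. An effect of the knockout on these sets, or on Foxc2, Hoxb2 and Hoxb3, thus cannot be told apart from weaker induction.

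In 2i the question was what Mesp1 does in naive cells, in 2 libraries against 2. Mesp1 was induced, from 1.09 and 0.613 CPM to 85.4 and 119. The Notch ligand gene Dll1 and Id4, which encodes an inhibitor of bHLH factors, had higher values in both dox libraries (log2 3.46 ± 0.55 and 2.04 ± 0.21), without passing edgeR's test (edgeR adjusted p = 1 and 0.892). Mesp1 itself did not pass (6.90 ± 0.36, edgeR adjusted p = 0.146), and was called without dox library 1 (0.000128) or 2 (0.00183). All 3 genes named had both dox libraries above both libraries without dox (33.3% by chance in either direction).

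edgeR called 0 of 18534 genes, with 385 at an unadjusted p below 0.05. The 385 are fewer than the share of 0.05 that unchanged genes would give. DESeq2 called 39 genes higher and 8 lower. With the replicate number as a block, edgeR called 333 higher and 300 lower, among them Mesp1 (6.95, edgeR adjusted p = 2.75e-15), Id4 (2.04, 1.21e-08) and Dll1 (3.53, 2.23e-06). Without dox library 1 it called 2, Mesp1 and Dio3 (outside the rule, noted after its values were seen), and without dox library 2 only Mesp1. No list member was called by edgeR. Camera gave primitive streak genes higher (median 0.26, camera adjusted p = 1.04e-06, 0.662 with an estimated correlation, with 1 of 12 higher adjusted over the list alone) and Notch genes higher (0.24, 0.025, 0.945), and neither held with an estimate. The 1 streak gene was Mesp1 itself, and without it the streak list was not called (camera adjusted p = 0.958, pointing down). The Mesp1-induced set had a median of 0.12 over 975 genes (camera adjusted p = 1.95e-05, 0.239 estimated) and the repressed set −0.05 over 1061 (0.297).

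The dox effect was tested for a difference between 2i and 24 h. The 673 genes with a lower effect in 2i included these that dox raised at 24 h: Aldh1a2 at −7.01 ± 0.77 (edgeR adjusted p = 1.87e-05), Pcdh19 at −7.38 ± 0.57 (1.29e-06), Tmem132c at −7.64 ± 0.71 (4.52e-06) and Foxc2 at −7.62 ± 1.54 (0.00441). The 777 with a higher effect included these that dox lowered at 24 h: Igfbp3 (4.26 ± 0.53, edgeR adjusted p = 5.6e-05), Slc27a2 (4.73, 0.000173) and Cxcl12 (4.21, 0.00212). A gene near 0 in 2i without dox has little room to fall there, so that a higher effect can reflect its level. edgeR called 1450 of 20600 genes in all. Higher and lower counts were 478 and 498 without 2i library 1 without dox, 556 and 420 without dox library 1, and 498 and 528 without dox library 2. Mesp1 was not called (2.37 ± 1.77, edgeR adjusted p = 0.583).

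Some of these calls were lost when a 2i library was left out. The fold fell with the call for Hoxb2 (−7.60, edgeR adjusted p = 0.0167) without library 2 without dox (−4.15, 0.997) and for Foxa2 (5.07, 0.0123) without dox library 2 (0.65, 0.995). Others kept most of their fold, Hoxb3 (−7.47, edgeR adjusted p = 0.00909) and Foxc2 without library 2 without dox (−6.82, 0.292, and −7.45, 0.0811), and Cxcl12 and the organizer gene Gsc (4.53, 0.00984) without dox library 2 (3.46, 0.0881, and 3.58, 0.118), Gsc also without library 1 without dox (4.03, 0.0556). Mixl1 (4.99, edgeR adjusted p = 0.0261) lost its call without any of the 4, at 4.62 (0.0816) and 5.72 (0.0646) without library 1 and 2 without dox and 4.97 (0.105) and 5.01 (0.0773) without dox library 1 and 2. Gsc had a mean of only 2.19 CPM without dox and 1.93 with dox in 2i. In the fit of 2i alone, 12 of the 15 primitive streak genes were tested. In the lists, epithelial genes gave 10 higher of 17 (13 adjusted over the list alone; median 2.04, camera adjusted p = 3.95e-19, 0.0178 with an estimated correlation), primitive streak 7 higher of 15 (10; 2.71, 3.11e-11, 0.0424) and primed epiblast 7 higher of 16 (8; 1.14, 9.77e-09, 0.0301). Mesenchymal genes gave 5 lower of 17 (9; −2.05, 4.6e-11, 0.0301), paraxial mesoderm 7 lower of 18 (10; −3.13, 9.77e-09, 0.0311) and early Hox 7 lower of 12 (7; −4.97, 8.02e-06, 0.0424). These 6 of the 16 lists that camera called held with an estimate.

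Sorting on day 4 asked what sets double positive cells, which carry both receptors of early cardiovascular mesoderm, apart from double negative ones. Kdr (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458) stood at 925 ± 291 CPM in double positive and 4.45 ± 1.91 in double negative cells, and Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215) at 404 ± 112 and 14.4 ± 2.08 (SD, n = 3), as the sort was made. The heart and lateral mesoderm genes Hand1 (5.48 ± 0.57, edgeR adjusted p = 0.000776), Hand2 (6.70, 0.000338) and Foxf1 (6.6 ± 0.72, 0.000917) were higher in double positive cells. Epithelial and endoderm genes were lower, such as the adhesion gene Epcam (−3.52 ± 0.19, edgeR adjusted p = 6.92e-05) and the endoderm factor gene Sox17 (−4.57 ± 0.34, 0.00024). Neither list held with an estimated correlation (camera adjusted p = 0.129 for each). Mesp1 was higher in double positive cells, at 76.3 ± 10.1 against 8.32 ± 1.27 CPM (3.22 ± 0.17, edgeR adjusted p = 6.92e-05).

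edgeR called 4318 of 16868 genes, 1587 higher and 2731 lower in double positive cells. The higher count fell to 927 and 879 without double negative library 3 and 5, and to 1006 without double positive library 3, with 2093, 2031 and 2103 lower. With same-numbered libraries paired as a block it called 7254 (3316 higher and 3938 lower), 4281 of them shared with the unpaired fit in the same direction. Kdr was higher by 7.73 ± 0.40 (edgeR adjusted p = 7.72e-05) and Pdgfra by 4.84 ± 0.25 (7.27e-05), and the strongest other genes higher were Unc5c (6.14, 0.00397) and Plxna4 (5.40, 0.000891). The strongest lower were Slc27a2 (−5.82, edgeR adjusted p = 0.000174), Eras (−5.18, 0.00178), Igfbp3 (−5.01, 0.00146), Cer1 (−4.85 ± 0.61, 0.0016), Cldn7 (−4.85, 0.000969) and Crb3 (−4.80, 0.00074). All 23 genes named had every double positive library beyond every double negative one, which a random split of 3 against 3 gives for 10% of unchanged genes.

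Of 16 cardiac progenitor regulators 13 were higher and 1 lower (13 and 1 adjusted over the list alone; median 3.47, camera adjusted p = 1.39e-16, 0.027 with an estimated correlation), such as Wnt2 (5.16, edgeR adjusted p = 9.44e-05) and Bmp4 (4.69, 0.000231). Of 16 mesenchymal genes 12 were higher, such as Zeb2 (2.34, edgeR adjusted p = 4.25e-05; list median 2.22, camera adjusted p = 4.47e-16, 0.027 estimated). These were the only lists to hold with an estimated correlation, and with the pairing as a block neither did (0.252 and 0.261). All 17 epithelial genes were lower, the epithelial regulator Grhl2 among them (−3.63, edgeR adjusted p = 6.92e-05; list median −3.96, camera adjusted p = 3.62e-21, 0.129 estimated). Definitive endoderm gave 10 lower and 1 higher of 12, such as Foxa2 (−4.70 ± 0.48, edgeR adjusted p = 0.000719) and Hhex (−3.22, 6.92e-05; list median −4.44, camera adjusted p = 2.55e-09, 0.129 estimated). Primed epiblast gave 10 lower and 2 higher of 16 (median −1.56, camera adjusted p = 1.3e-05, 0.104 estimated). The forebrain gene Six3 was lower (−5.50, edgeR adjusted p = 0.000164). Proliferation genes gave 12 higher of 15 (15 over the list alone; median 0.63, camera adjusted p = 2.42e-05, 0.48 estimated). Endothelial genes gave 5 higher and 3 lower of 15 (camera adjusted p = 0.0368, 0.509 estimated) and early Hox genes 3 higher of 4 (0.000358, 0.255). The Nodal median was 0.95 while the test pointed down (camera adjusted p = 0.88). With the block, camera no longer called BMP response (0.00367 to 0.0864) and primordial germ cell genes (0.0256 to 0.0954), and newly called paraxial mesoderm (0.0173), FGF response (0.00401) and Notch genes (0.0311), none of which held with an estimated correlation (adjusted p = 0.261, 0.261 and 0.296).

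Double positive cells were also set against unsorted day 4 cells, 2 libraries against 2. Kdr and Pdgfra were enriched, by 3.30 ± 0.34 (edgeR adjusted p = 0.00238) and 1.35 ± 0.19 (0.00359), and so were the heart mesoderm genes Tbx2 (7.64 ± 0.74, 0.00196), Hand1 (5.53 ± 0.53, 0.00191) and Foxf1 (6.4, 0.00383). Mesp1 was not (0.15 ± 0.32, edgeR adjusted p = 0.71). The pluripotency gene Utf1 was lower (−6.19 ± 0.31, edgeR adjusted p = 5.87e-05), as was Fam19a4 (−6.17 ± 0.35, 9.66e-05). Against the same 2 bulk libraries, which both comparisons share, double positive replicates 3 to 5 gave 3.37 for Kdr, 1.45 for Pdgfra, 8.14 for Tbx2, 6.17 for Hand1, 6.69 for Foxf1, −5.97 for Utf1 and −7.40 for Fam19a4, all called by edgeR.

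Other genes were set apart only, or mainly, in replicates 1 and 2. The cyclophilin gene Ppia was higher by 5.69 ± 0.13 (edgeR adjusted p = 6.14e-06; 566 against 12.2 CPM) and by 0.70 in replicates 3 to 5 (0.0258), and the ribosomal gene Rpl24 by 5.72 ± 0.14 (6.87e-06) and −0.30 (0.209). The retrotransposed copies Aldoart1 (−7.24 ± 0.19, edgeR adjusted p = 8.56e-06), Uchl4 (−7.01, 1.03e-05), Rbm8a2 (−6.80, 2.54e-05) and Tpm3-rs7 (−5.90 ± 0.16, 8.56e-06) stood at −2.31 (0.000424), −0.20 (0.29), −1.40 (0.00055) and 0.07 (0.672) in replicates 3 to 5. edgeR called 10010 of 19350 genes, 4437 higher and 5573 lower, against 6824 of 17381 with replicates 3 to 5, with 5246 called the same way by both and 265 opposite ways. Without bulk library 1 or 2 it called 4903 (1642 higher and 3261 lower) and 5009 (1648 and 3361). Of the 15 genes named, 14 had both double positive libraries beyond both bulk libraries (33.3% by chance), the exception being Mesp1 (1 of 2), which changed sign without bulk library 1 (−0.05) or double positive library 1 (−0.33).

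**Figure D4:**
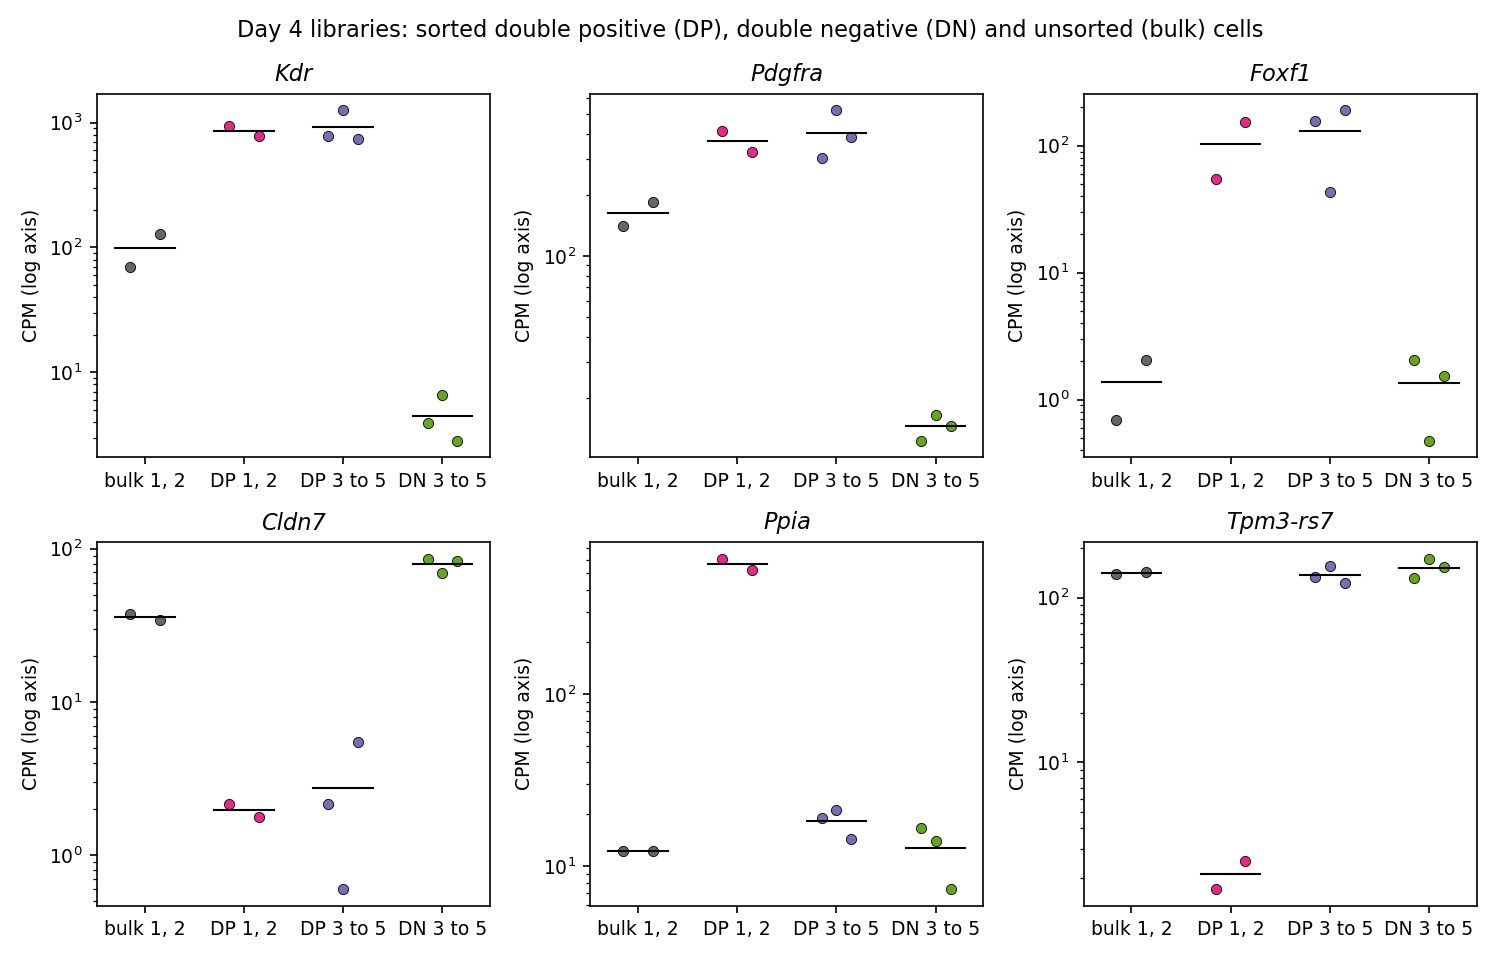
Kdr, Pdgfra, Foxf1, Cldn7, Ppia and Tpm3-rs7 in the day 4 libraries, as CPM on a log axis for bulk, double positive replicates 1 and 2, double positive replicates 3 to 5 and double negative cells. Points are libraries and lines are means; Ppia and Tpm3-rs7 set double positive replicates 1 and 2 apart, while Kdr, Pdgfra and Foxf1 were enriched in both sets.

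Several of these calls needed both libraries of a group, while the folds stayed near the full ones. Kdr lost its call without double positive library 1 (3.12, edgeR adjusted p = 0.12) or 2 (3.45, 0.118), and Pdgfra likewise (1.15, 0.0676, and 1.52, 0.051). Without bulk library 1 the call was lost by Hand1 (5.28, edgeR adjusted p = 0.126), Tbx2 (7.71, 0.0513), Foxf1 (5.8, 0.161) and Unc5c (6.76, 0.289; 7.08, 0.00974 with all), and without bulk library 2 by Hand1 (5.8, 0.111), Foxf1 (7.36, 0.134) and Unc5c (7.47, 0.266), while Foxf1 also lost it without double positive library 2 (5.51, 0.0591). Of 18 cardiac progenitor regulators 15 were higher and 1 lower (16 and 1 adjusted over the list alone; median 2.89, camera adjusted p = 1.3e-05, 0.66 with an estimated correlation), and with replicates 3 to 5 it was 16 and 1 (3.49, 1.14e-11, 0.142). Epithelial genes gave 15 lower of 17 (median −2.92, camera adjusted p = 9.85e-09, 0.492 estimated), and mesenchymal genes 11 higher of 17 (1.09, 0.00462, 0.66). Naive pluripotency genes gave 13 lower and 3 higher of 18 (median −2.02, camera adjusted p = 0.0754, 0.66 estimated), and primitive streak 8 lower of 15 (−2.38, 0.00275, 0.66). For primordial germ cell genes the median was −3.08, or −2.45 with the gene at 0 held at its bound. Camera also called dissociation stress genes, with 9 lower and 1 higher of 15 (camera adjusted p = 0.0398, 0.66 estimated). Blood genes gave 4 higher and 1 lower of 8 (0.0358, 0.66) and definitive endoderm 8 lower and 2 higher of 12 (0.0163, 0.66). None of the 10 lists called by camera held with an estimate.

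Last, genes that changed with dox at 24 h, the Mesp1-induced and Mesp1-repressed sets, were followed in sorted cells. Of 1117 Mesp1-repressed genes tested, 829 were lower and 10 higher in double positive than in double negative cells (902 and 16 adjusted over the list alone, a set chosen in other libraries; median −1.94, camera adjusted p = 4.08e-70, 0.00478 with an estimated correlation). With the pairing as a block the set did not hold with an estimate (0.104). Foxa2, Eras and Cldn7 were among those lower in both. Of 1089 Mesp1-induced genes 437 were higher and 100 lower (492 and 118 over the list alone; median 0.57, camera adjusted p = 6.17e-18, 0.135 estimated), Pdgfra, Foxf1 and Wnt2 among those higher in both. Against bulk, 694 of 1264 induced genes were higher and 99 lower (median 0.91, camera adjusted p = 2.64e-13, 0.182 estimated), and 1021 of 1320 repressed genes were lower and 18 higher (−1.81, 5.91e-21, 0.135). Gene by gene, 724 genes rose with dox at 24 h and were higher in double positive than double negative cells, and 1292 fell and were lower, where independent lists would share 241.9 and 388.5. With the pairing as a block these were 1006 and 1537, where 506.2 and 565 would be by chance. Genes that rose but were lower, and fell but were higher, numbered 207 and 51 unpaired and 368 and 176 with the block. With double positive replicates 3 to 5 against bulk the shared genes were 1174 and 1393, where 491.3 and 470.6 would be by chance.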

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

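The tests of gene copies and depth for batch 2 the 4 tests on 2i and the splits kept within batches were chosen only after the result was seen.

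Among 4 libraries of batch 2 at 24 h with dox, 47 quantities were examined for 1 library far from the other 3 (Dixon's test). Of these, 9 met the limit. Chance gives about 1 in 20 groups for independent, normal values. CPM was not put on a log scale, and many of the genes were named because dox changed them, so that this rate need not hold. Dox library 1 stood apart in 6 of the 9. It had 258 CPM of Foxc2 (the others 55.6 to 89.1), 26.4 of Foxf1 (9.39 to 11.1), 15.8 of Klf4 (5.29 to 6.8), 66.9 of Myocd (6.15 to 16.5), 52.3 of Pgm5 (9.06 to 13.2) and 126 of Twist1 (39.7 to 41.6). It also had the highest Mesp1 of the 4, at 544 CPM. Dox library 2 was low in Cxcr4 (72.7, the others 113 to 117), library 3 in Foxh1 (176, 226 to 236) and library 4 in Foxa2 (1.49, 2.57 to 2.67). Among the 5 double positive libraries, 36 quantities gave 1, Hhex at 9.07 CPM in library 1 (6.64 to 7.25 in the others).

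The effect of dox differed between 24 h and 12 h by a test of the difference itself for 97 genes. With 12 h in batch 1 only and 24 h in both batches, this difference also carries one between batches. It was higher at 24 h for Fhod3 (2.91), Pde8b (2.12), Igsf11 (2.40), Nhsl2 (2.06), Unc5c (3.27) and Rasgrf1 (5.2), and lower for Bcl11b (−2.77), Eras (−2.71), Slc27a2 (−2.73), Foxa2 (−3.06), Fam19a4 (−2.88) and Egr1 (−3.34). Leaving out either 12 h library without dox brought the count to 1 and ended the call of all 12. Between batches the dox effect at 24 h differed for 117 genes. It was higher in batch 2 for Hs3st3b1 (5.12), Cxcr4 (4.64), Fgf3 (5.52), Klhl6 (5.91), Robo3 (4.94) and Prss12 (4.40), and lower for Map3k15 (−1.69), Serinc5 (−1.47), Ccn2 (−2.26), Aifm2 (−2.65) and Car3 (−1.57). Between 2i and 24 h it differed for 1450 genes. It was higher in 2i for Igfbp3 (4.26), Slc27a2 (4.73), Cxcl12 (4.21), Gsc (4.53), Foxa2 (5.07) and Mixl1 (4.99), and lower for Pcdh19 (−7.38), Tmem132c (−7.64), Aldh1a2 (−7.01), Foxc2 (−7.62), Hoxb3 (−7.47) and Hoxb2 (−7.60).

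In batch 2, 158 genes expressed in batch 1 had no count in any library. Exons of 97.37% of those with coordinates (148 of 152) overlapped exons of another gene, against 39.48% of genes matched on level, so that a candidate explanation is that reads over shared exons were counted differently in batch 2. Gene copies do not account for most of them, since 5.96% (9 of 151) had copies, and depth is excluded, since a median of 4166 counts would have been expected. HTSeq's tally of reads with too low alignment quality was 0 in all 8 batch 2 libraries, and in 0 of the 10 batch 1 libraries. No biological explanation was tested.

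In 2i no gene was called by edgeR after Mesp1 induction (385 at an unadjusted p below 0.05; 47 called by DESeq2, and 633 by edgeR with the replicate number as a block, though the number is not shown to pair these libraries), while 5584 were at 24 h. The number of libraries does not account for this alone, since 4 batch 1 libraries at 24 h, also 2 against 2, called 2600 genes. A larger spread hiding changes of the same size does not account for most genes that rose at 24 h. The 975 of them tested in 2i had a median of 0.12 and an upper quartile of 0.43 there. The whole set had a median of 1.80 at 24 h. Mesp1 itself rose by 6.90 in 2i without a call (edgeR adjusted p = 0.146), so that spread could hide single large changes. The 385 genes at an unadjusted p below 0.05 were also fewer than unchanged genes would give. A lower Mesp1 level does not account alone for the lack of calls in 2i (85.4 and 119 CPM, against a 24 h dox median of 196.2). Batch 2 dox libraries 3 and 4, at 42.9 and 95.2 CPM, called 5110 genes against batch 2 without dox. Their median was 1.99 for 867 genes that rose in batch 1 (1.96 there, 0.14 in 2i). The state of the cells, which the labels name, may also matter and was not tested.

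Double positive replicates 1 and 2 against bulk called 1249 genes with at least a 2-fold change that replicates 3 to 5 neither called nor changed 2-fold, of 17348 tested in both. Of those searched, 36.8% (457 of 1242) had copies elsewhere in the transcriptome, against 5.466% of matched genes, so that a candidate explanation for part of the pattern is that reads from near-identical copies were counted differently in these 2 libraries. With the bulk counts thinned to the depth of the double positive libraries, 96.16% were still called. Both comparisons used the same bulk libraries, so that this test does not bear on why they differ. Reads not uniquely aligned made up 15.76% to 15.94% in replicates 1 and 2, 6.098% to 6.488% in replicates 3 to 5 and 7.302% to 7.449% in bulk. A different sorted population stays open and was not tested.

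Other splits of the same libraries were fitted to see how many genes they call. At 24 h of dox, 100 of the 210 possible splits were fitted, the real one and a random draw of others. Of these 1, the real one, called as many as 5584, and the highest other drawn called 751. Of the 90 splits that keep the number of libraries of each batch on each side, which were all fitted, only the real one called as many. That is a share of 0.0111, the smallest these splits can give, and the highest other called 2892. Chance is thus unlikely but not excluded. For 24 h against 0 h without dox, 1 of 35 splits, the real one, called as many as 4675, and the highest other called 18. Some of these splits move libraries across batches, so that this share does not decide on chance. There the splits that keep each batch balanced number 18, too few for a share under 0.05, so that chance within batches stays open. For double positive against double negative cells the 10 splits are too few for a share under 0.05, with 4318 genes for the real split and 0 for the highest other.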

How the results depend on the processing

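The tests on genes without exon overlap and on double positive replicates 3 to 5 against bulk were chosen only after the result was seen. So were the tests without batch 2 dox libraries 1 and 2, and with either block for double positive against bulk. The same holds for the block for the Mesp1 sets and the streak list without Mesp1. It also holds for all alternative fits of genes for the differences between batches and between 2i and 24 h. The list tests of these differences with an estimated correlation or fry were planned.

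Total counts of called genes stayed within 1.5 times the reported one except as follows, and the cause was not tested unless given. With no count filter the count was 1628 at 12 h of dox, 605 for 12 h against 0 h, 873 for the difference between 24 h and 12 h, 514 for that between batches and 18 in 2i. With DESeq2 it was 245 for 12 h against 0 h, 488 for 24 h minus 12 h, 260 between batches, 5 in the knockout and 47 in 2i. With fewer samples, batch 2 alone gave 3118 at 24 h of dox and 658 for 24 h against 0 h, which without a batch term gave 2089. Fitting only the groups compared gave 488 for 12 h against 0 h, and 2i fitted with batches 1 and 2 gave 22. Genes without exon overlap, fewer genes tested, gave 963 for 2i minus 24 h, 2778 for double positive against double negative and 6414 against bulk. All 5 double positive libraries against bulk gave 5112. Without batch 2 dox libraries 1 and 2 the difference between batches gave 177. In 1 direction alone, the count moved further for DESeq2 at 12 h of dox (670 lower), for no count filter in 2i minus 24 h (1018 lower), for double positive replicates 3 to 5 against bulk (3496 lower), and for genes without exon overlap at 24 h (1831 higher) and 12 h of dox (392 higher), 12 h against 0 h (4 lower) and between batches (4 lower).

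With the replicate number as a block the count was 309 for 24 h minus 12 h, 633 in 2i and 7254 for double positive against double negative cells. Only these sorted cells had the 3 pairs needed to judge pairing. Elsewhere there were 2 pairs, whose deviations correlated at 0.83 in 2i and at 0.81 and 0.68 in batch 1 at 24 h and 12 h of dox, but 2 pairs cannot show pairing and the labels give no shared origin. Between double positive and double negative cells the block changed no call of a named gene. With an estimated correlation both Mesp1 sets stood at 0.104 with the block, which ended the call of the repressed set, and the gene lists it changed are given with their results. It changed no other call reported for these cells. Double positive against bulk gave 8706 genes with the block and 9458 with the numbers crossed.

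Leaving out 1 library, where a lone sample is assumed to vary like other groups, gave 423 to 693 genes at 12 h of dox, 5 to 68 for 12 h against 0 h, 1 to 249 for 24 h minus 12 h, 22 to 237 between batches, 0 to 9 in the knockout, 0 to 2 in 2i and 4903 to 12394 for double positive against bulk. By direction, higher and lower counts ran from 0 to 84 and 1 to 165 for 24 h minus 12 h and from 20 to 190 and 2 to 47 between batches. The lower count for 12 h against 0 h ran from 0 to 14, and the higher count for double positive against double negative cells from 879 to 1727. The cause beyond fewer samples was not tested.

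Of 253 list tests, 163 kept their side of the threshold with an estimated correlation and 90 lost the call. With fry 202 kept it, 37 lost it, 9 gained it and 5 changed direction, none of them called by fry: paraxial mesoderm for 24 h minus 12 h (adjusted p = 0.985), cardiomyocyte (0.997) and trophoblast (0.581) lists in double positive against double negative cells, and visceral endoderm (0.51) and Notch (0.524) lists against bulk. Fry does not compare a list with other genes, and the cause was not tested.

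The number of lists called fell with an estimated correlation from 15 to 9 at 24 h of dox, 10 to 2 at 12 h, 9 to 0 for 24 h against 0 h, 5 to 1 for 12 h against 0 h, 14 to 0 for 24 h minus 12 h, 17 to 8 between batches, 8 to 0 in the knockout, 2 to 0 in 2i, 16 to 6 for 2i minus 24 h, 12 to 2 for double positive against double negative and 10 to 0 against bulk. With fry it was 6 at 12 h of dox, 1 for 12 h against 0 h, 8 between batches, 0 in the knockout and 0 in 2i. The Mesp1 sets lost their call with an estimate in the knockout (induced 0.154, repressed 0.135), in 2i (induced 0.239), in double positive against double negative cells (induced 0.135) and against bulk (induced 0.182, repressed 0.135), and with fry in the knockout (0.176 and 0.148) and 2i (induced 0.362). A larger correlation widens the null by construction. With Mesp1 left out of the primitive streak list, camera at the preset correlation lost its call in 2i, where it pointed down (0.958), and called it between double positive and double negative cells with the block (0.25 to 0.0159, or 0.329 with an estimate). Fry called it against bulk (0.0522 to 0.0435).

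Of 188 named results, 171 were called, 111 of them under all alternatives, and 60 lost the call at least once. Direction changed, from a cause not tested, for Mesp2 in batch 2 alone (0.11), Zic1 (leave-one-out range −0.24 to 0.42), Zic5 (−1.12 to 0.70, with −0.32 without wild-type library 2 and −0.10 with the block), Mesp1 against bulk (−0.05 without bulk library 1, −0.33 without double positive library 1), and with double positive replicates 3 to 5 for Rpl24 (−0.30) and Tpm3-rs7 (0.07). At these depths 1 count stood for 0.0193 to 0.0825 CPM, which limits genes near 0.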
